A study of Rattus norvegicus with 20 samples.

How the data were processed

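Messenger RNA was measured in the right ventricle (RV) and left ventricle (LV) of male rats given monocrotaline (MCT) or saline. MCT is a plant alkaloid that injures lung vessels and is used to raise pressure in the lung circulation. Per the labels, rats were injected at a weight of 250 g with 60 mg/kg MCT or with saline, and were killed at a discomfort score of at least 7. Total RNA was made into QuantSeq libraries, which read the 3' ends of transcripts, and sequenced as 150 bp read pairs. The 20 libraries formed 4 groups of 5, taken from the labels with their replicate numbers.

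The values used were raw read counts per Ensembl gene, as deposited, with 1 column per library. Per the submitters' processing notes, STAR 2.7.10a and HTSeq 0.11.3 were used, with the builds mRatBN7.2 and rn6 named without their roles. The strand setting, the annotation release and the way reads of separate sequencing runs were joined are not given in the sources used here. Overlapping genes and near-identical copies could therefore share counts. All 30452 rows carried a gene ID and all columns were matched to a sample. The totals ran from 3272420 to 9227104 counts, which limits the precision for weakly expressed genes.

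The files do not pair the IDs with gene names, and the reference gene table used (assembly GRCr8) held an Ensembl ID for 0 of its genes, so none of the 30452 IDs could be looked up in it. The gene lists fixed before the data were examined, and the genes fixed by symbol, could therefore not be tested. For the same reason at most 2 IDs that rose and 2 that fell are printed. They were the RV genes with the largest rise and the LV genes with the largest fall among those with an adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap between the libraries of both groups. The rule had been fixed beforehand except that it also asked for a symbol. The choice of RV risers and LV fallers was made after the data were seen.

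The counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalization, the filterByExpr filter, a robust quasi-likelihood fit of the 4 group means over all 20 libraries, and Benjamini-Hochberg adjustment with a threshold of 0.05. Of all genes, 10929 passed the filter and held 99.8% of the counts. The standard error of a log2 fold change was derived from the quasi-likelihood F statistic. Log2 CPM for principal components used a prior count of 2. Genes detected were compared at the lowest total count by rarefaction with vegan 2.7.1. The comparisons were MCT against saline in the RV and in the LV, the difference of these responses, and RV against LV within each treatment. Tests, groups and most alternatives were fixed before the data were examined.

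On simulated counts for 10929 genes of which 200 were changed, the RV comparison recovered 55% of genes changed 2-fold and 92% of those changed 4-fold, with 5 false calls. The LV comparison recovered 49% and 85%, with 3 false calls. With no gene changed, the RV simulation gave 1 call and the LV simulation gave 0. The simulated genes varied independently of each other around the saline means, with no library that deviated as a whole. Some real libraries did deviate in this way, so these rates may not hold for the real comparisons.

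RV and LV libraries of one treatment share replicate numbers and description codes, which look like dates. The labels do not state in words that they come from the same animals, so the main design had no block. Nor do they state that the libraries of a group come from separate animals, so p-values measure the spread between these libraries. No 2 libraries of a group had identical counts. Over the 40 pairs within groups, the chi-square per degree of freedom ran from 5.41 to 154, so no pair agreed within sampling noise. The codes read as May or June for 3 libraries of each group and as November for 2.

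Alternatives were RLE normalization, other filters on low counts (none, or at least 1 CPM in at least 5 libraries), the month as a batch term, only the groups compared, a replicate block, leaving out each library in turn, DESeq2 1.42.0, and limma 3.58.1 voom with quality weights. Fits within each month were run as a check of batches.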

Results

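Gene expression was measured in 20 ventricle libraries from rats given MCT or saline, with 5 libraries each of RV MCT, RV saline, LV MCT and LV saline. The question was how each ventricle responds when MCT is used to model pulmonary hypertension. Total counts averaged 5410170 ± 1796050 (SD, n = 5) in RV MCT, 5273230 ± 1219940 in RV saline, 5820310 ± 2546890 in LV MCT and 5011600 ± 1190190 in LV saline. Between 13542 and 15760 genes had at least 1 count in a library. The 10 genes with most counts took from 25.7% of a library, in LV MCT replicate 1, to 50.2%, in RV saline replicate 3.

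The first principal component held 32.0% of the variance and the second 20.2%. On the first, LV MCT libraries averaged 23.7 ± 26.3 (SD, n = 5) and LV saline libraries -24.6 ± 4.81. RV MCT libraries averaged 20.4 ± 35.3 and RV saline libraries -19.6 ± 6.86. In the exact two-sided permutation test the difference had p = 0.024 in the LV and p = 0.048 in the RV. Over the 10 relations tested between treatment and library measures, the Benjamini-Hochberg values were 0.12 and 0.14. LV MCT replicate 3, at -21.0, and RV MCT replicate 4, at -30.3, lay among the saline libraries. The other 8 MCT libraries lay above all saline libraries.

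**Figure D1:**
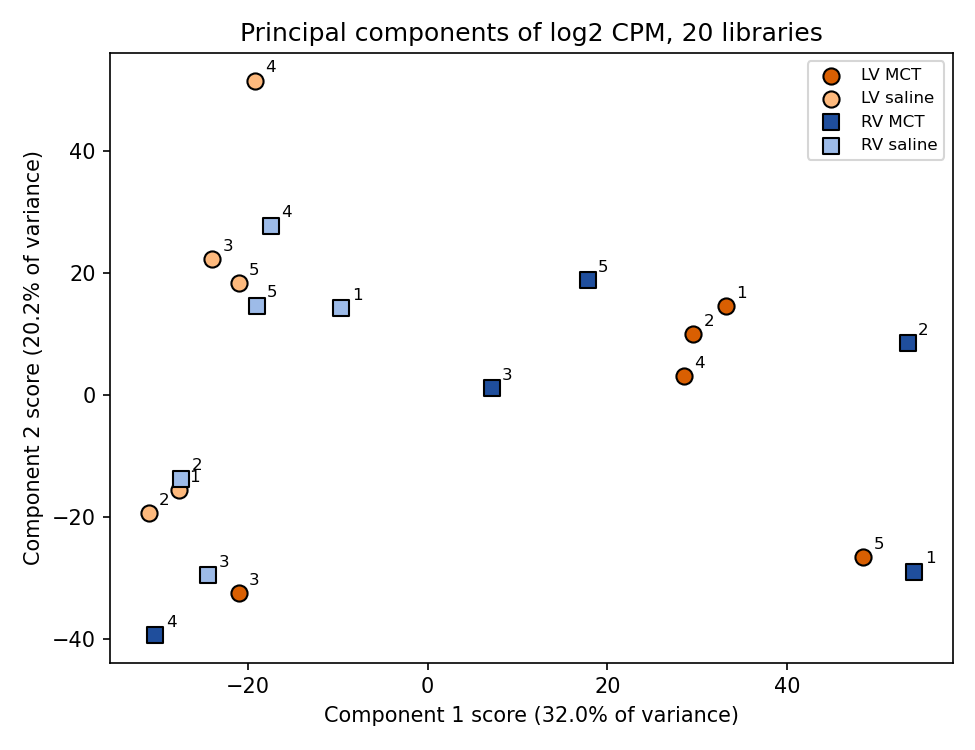
Scores of the 20 libraries on the first and second principal components of log2 CPM, with colour and shape for the group and numbers for replicates. LV MCT replicate 3 (-21.0) and RV MCT replicate 4 (-30.3) sit among the saline libraries on the first component.

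In the LV, MCT changed 1040 of 10929 genes, of which 596 were higher and 444 lower than after saline (edgeR quasi-likelihood test, adjusted p under 0.05). The median log2 fold change was 1.21 among higher genes and -0.79 among lower genes. Of the higher genes 386 rose by over 2-fold, 89 by over 4-fold and 25 by over 8-fold. Of the lower genes 108 fell by over 2-fold and 9 by over 4-fold. The genes that fell were more strongly expressed, with a median log2 CPM of 5.55 against 3.57 for those that rose. Genes higher after MCT held 2.61% ± 0.946 (SD, n = 5) of the counts in LV MCT libraries and 0.871% ± 0.0435 in LV saline libraries. Genes lower after MCT held 22.8% ± 1.99 and 31.8% ± 4.49. Both sets were chosen for these changes, so the shares describe their size and do not test them. In 769 genes, or 7.04%, the LV groups did not overlap, where chance gives 0.794%, and of these 351 were higher and 418 lower after MCT.

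The LV count depended on single libraries. It was 1699 without LV MCT replicate 3. Without LV MCT replicate 1, 4 or 5 it was 506, 470 or 331, and without LV saline replicate 3, 4 or 5 it was 534, 450 or 483. The replicate block gave 356 genes and limma voom gave 2892. Within the May and June libraries, 3 per group, no LV gene was called and 1329 had an unadjusted p under 0.05. Within the November libraries, 2 per group, 243 were called.

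In the RV, MCT changed 30 genes, of which 26 were higher and 4 lower (edgeR quasi-likelihood test, adjusted p under 0.05). All 26 rose by over 2-fold and 15 by over 4-fold, and the median log2 fold change was 2.11 among higher genes and -1.55 among lower genes. At an unadjusted p under 0.05 there were 1914 genes, where 546 were expected by chance. In 260 genes, or 2.38%, the RV groups did not overlap, where chance gives 0.794%, and of these 105 were higher and 155 lower after MCT. The excess of rises among the 30 genes was also absent with limma voom, which called 123 higher and 130 lower. It was kept with RLE normalization (25 higher, 3 lower) and without a filter on low counts (16 and 2). Within the May and June libraries 123 were higher and 65 lower.

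The RV count was not stable. It was 707 without RV MCT replicate 4, 249 without RV MCT replicate 3 and 144 without RV MCT replicate 5, and each of these fits called all 30 genes. It was 2 without RV MCT replicate 1, 3 without RV MCT replicate 2, 0 without RV saline replicate 1 or 4, and 2 without RV saline replicate 2, 3 or 5. No gene was called when only the RV libraries were fitted or with the replicate block, while DESeq2 called 378 and limma voom 253. Without a filter on low counts 18 genes were called, and with the month as a batch term 19. Within the May and June libraries 188 genes were called, and within the November libraries 0. In each ventricle the set with 0 calls held the MCT library that lay among the saline libraries. These were RV MCT replicate 4 in November and LV MCT replicate 3 in May and June. Effects of the month and of these libraries cannot be told apart here.

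**Figure D2:**
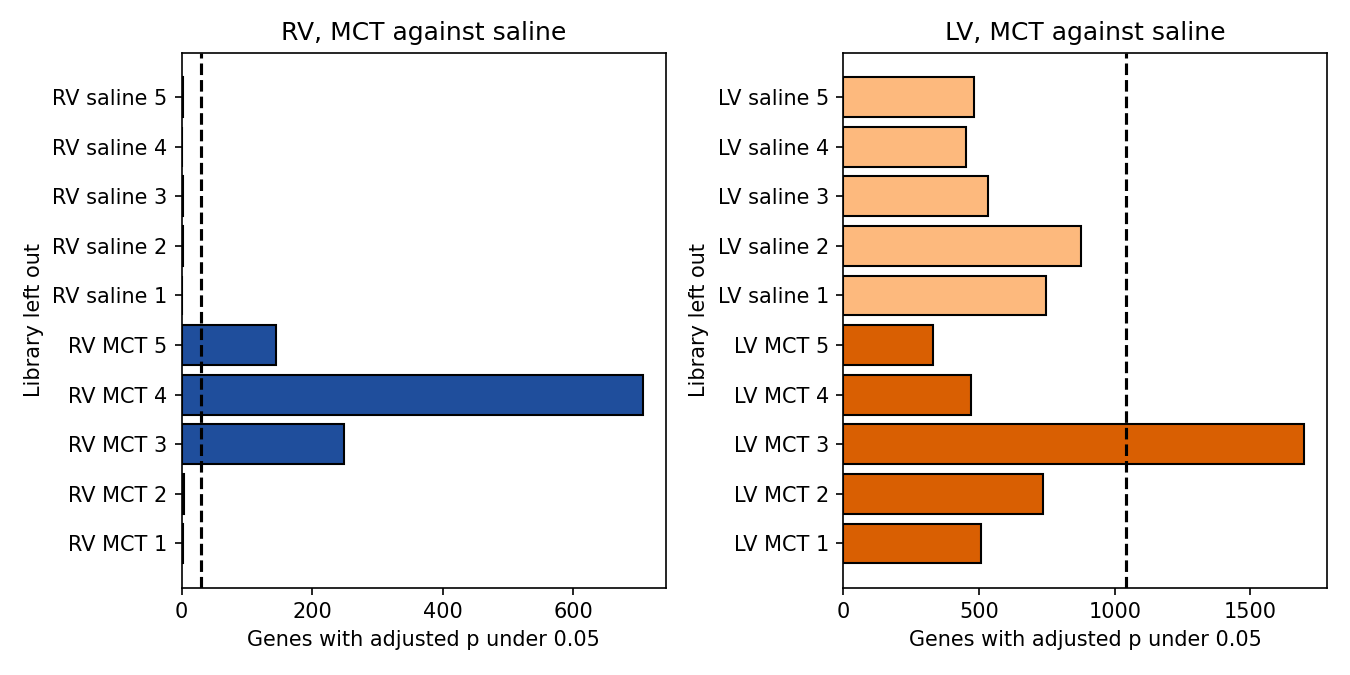
Number of genes with an adjusted p under 0.05 for MCT against saline in the RV (left) and LV (right) when the library on the vertical axis is left out, with dashed lines at the counts from all libraries. The RV count ran from 0 to 707 around 30 and the LV count from 331 to 1699 around 1040.

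The gene ENSRNOG00000002434 rose after MCT in both ventricles. In the RV it was at 53.1 ± 37.5 CPM (SD, n = 5) after MCT and 10.8 ± 2.75 CPM after saline, a log2 fold change of 2.30 (SE 0.45, edgeR adjusted p = 0.029). In the LV it was at 64.1 ± 28.7 and 9.67 ± 1.63 CPM, a log2 fold change of 2.73 (SE 0.46, edgeR adjusted p = 0.0075). The gene ENSRNOG00000009325 also rose in both. Its log2 fold change was 1.502 in the RV (SE 0.27, edgeR adjusted p = 0.028) and 0.92 in the LV (SE 0.27, edgeR adjusted p = 0.034). The RV calls of both genes were lost under some alternatives, with adjusted p up to 0.27, and so was the LV call of ENSRNOG00000009325, with adjusted p up to 0.10.

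The genes ENSRNOG00000019719 and ENSRNOG00000002916 fell in the LV. ENSRNOG00000019719 was at 9.54 ± 9.09 CPM (SD, n = 5) after MCT and 36.2 ± 5.34 CPM after saline, a log2 fold change of -1.999 (SE 0.55, edgeR adjusted p = 0.028). ENSRNOG00000002916 was at 11.2 ± 10.4 and 36.5 ± 5.10 CPM, a log2 fold change of -1.78 (SE 0.50, edgeR adjusted p = 0.030). Both calls were lost without LV MCT replicate 1 (adjusted p = 0.074 and 0.079), and in 7 and 9 of 20 alternatives, with adjusted p up to 0.075 and 0.082. Their RV log2 fold changes were -1.54 (adjusted p = 0.14) and -1.33 (adjusted p = 0.17), which did not pass the threshold. With limma voom both passed in the RV (adjusted p = 0.047 and 0.039), and ENSRNOG00000002916 also passed without RV MCT replicate 4 (edgeR adjusted p = 0.039).

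**Figure D3:**
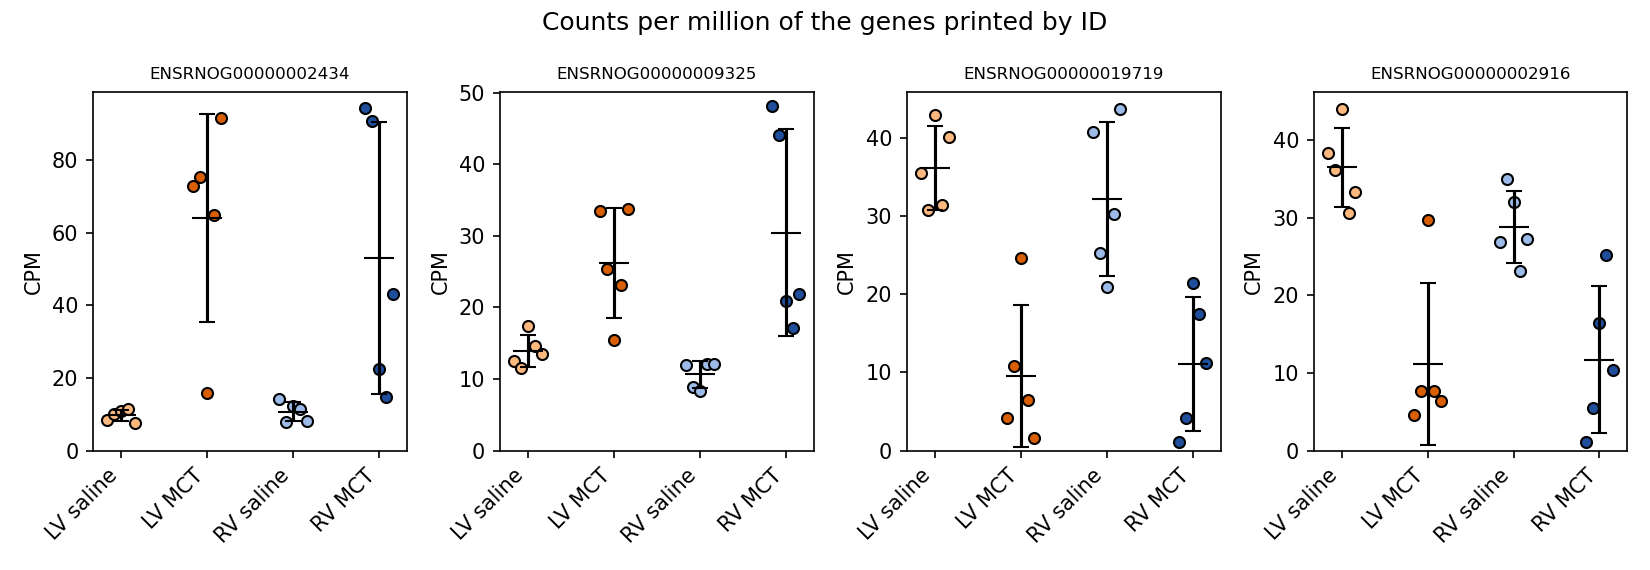
Expression in CPM (counts scaled by library totals that were adjusted by TMM normalization) of the 4 genes printed by ID in each library (points), with the mean and SD of each group of 5 (bars). In LV MCT replicate 3 the level of ENSRNOG00000002916 was 29.7 CPM, against 4.62 to 7.69 CPM in the other LV MCT libraries.

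The responses of both ventricles were compared directly. No gene was called for a response that differed between RV and LV (edgeR, smallest adjusted p = 0.85). At an unadjusted p under 0.05 there were 305 genes, where 546 were expected by chance. The median SE was 0.35 for this difference, against 0.24 for the RV response and 0.25 for the LV response. The lack of calls therefore does not show that the responses were alike. DESeq2 called 1 gene and limma voom called 0. The larger number of genes called in the LV is therefore not shown to be a difference between the ventricles. Of the 26 genes that rose in the RV, 19 were also called higher in the LV, where independent lists would share 1.42. Of the 4 that fell in the RV, 2 were called lower in the LV, where independent lists would share 0.163. Same-numbered libraries may share animals, so the lists may not be independent. No value without an effect is given for these overlaps or for the signs below. Of the LV genes, 585 of the 596 that rose and 443 of the 444 that fell had the same sign in the RV, with median RV log2 fold changes of 0.74 and -0.47.

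Across the 10929 genes, which are not independent replicates, the log2 fold changes of RV and LV had a Pearson correlation of 0.75 and a Spearman correlation of 0.69. Without a filter on low counts the Pearson value was 0.31. With separate replicate numbers for each ventricle, in differences of means of only 2 or 3 libraries, it was 0.54 and 0.57. Within the May and June libraries the Pearson value was 0.66, and within the November libraries it was 0.55. For differences of group means over all libraries, the correlation was 0.74 and the covariance 0.18. With separate replicate numbers the covariances were 0.18 and 0.16, so the lower correlations there came with little change in covariance. Over 100 splits of the same-numbered RV and LV pairs with the group means removed, the correlation had a median of 0.084 and ran from -0.40 to 0.69. The covariance in those splits had a median of 0.0066 and reached 0.12.

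**Figure D4:**
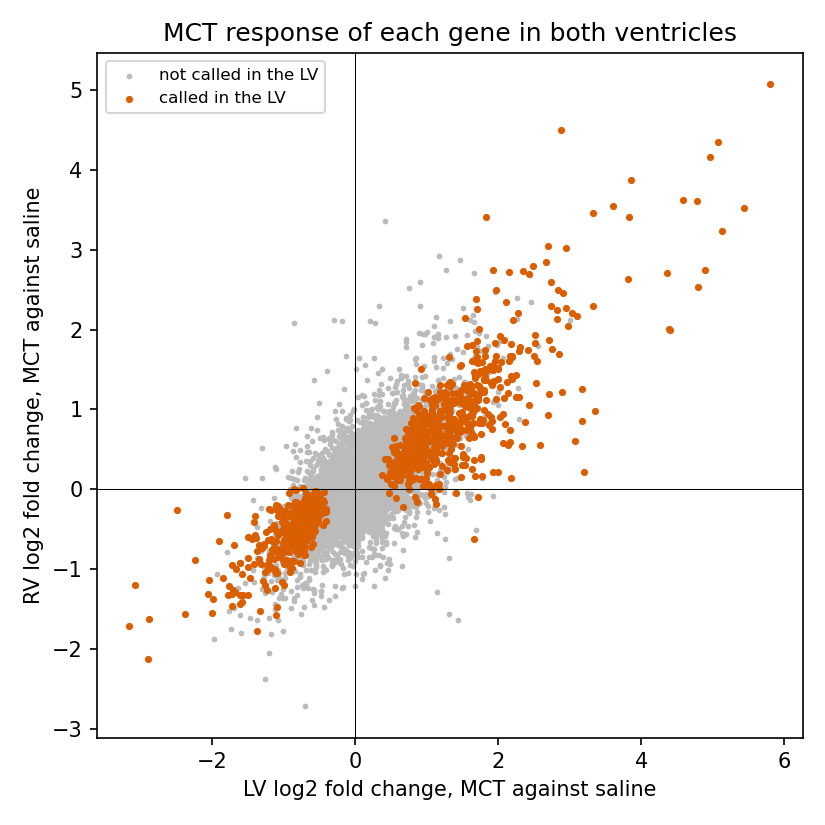
Log2 fold change of each of the 10929 genes after MCT in the LV (horizontal) and the RV (vertical), with genes called in the LV in orange. Of the 596 genes called higher in the LV, 585 lay above 0 in the RV.

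RV and LV were also compared within each treatment. After saline 8 genes differed, 6 higher and 2 lower in the RV (edgeR, adjusted p under 0.05). With RLE normalization 7 were higher and 6 lower, so the balance of directions was not stable. At an unadjusted p under 0.05 there were 909 genes, where 546 were expected by chance. Of these 8 genes, 2 were also called with each same-numbered RV and LV pair as a block. When only the saline libraries were fitted 80 genes were called, and DESeq2 called 88. Without RV saline replicate 1 the count was 0, without LV saline replicate 2, 3 or 5 it was 4, 5 or 2, and without RV saline replicate 3 it was 2. After MCT no gene differed (edgeR, smallest adjusted p = 0.99996), and DESeq2 and limma voom also called 0. At an unadjusted p under 0.05 there were 203 genes, where 546 were expected by chance. The lack of calls therefore does not show that the ventricles were alike. Without RV MCT replicate 5, 2 genes were called.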

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

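Apart from the counts over splits, the tests of explanations here were chosen after the results were seen. The bounds for a weak response and for the share of top genes were changed once after a first outcome was known. A library was taken as far from its group when its gap to the next library was a large share of the group's range. Of 42 sets of 5 values looked at, 2 were picked out, and chance picks about 1 in 20. These were the first component score of LV MCT replicate 3, at -21.0, and its level of ENSRNOG00000002916, at 29.7 CPM.

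LV MCT replicate 3 lay among the saline libraries. Low depth is argued against: with every library thinned to the lowest total, 4 of the other 4 LV MCT libraries stayed above the highest LV saline library. A library from another animal than RV MCT replicate 3 is only weakly argued against. The libraries had 0 differences between them at 8 genes, called on-off genes, that split the saline libraries into a high and a low side. These genes are few, and the low side need not be without expression. A few genes taking many counts cannot be told apart, since the interval predicted from the share of the 10 top genes reached from -38.0 to 67.1. If same-numbered libraries share an animal, a weak response of it may remain: RV MCT replicate 3 scored 7.12, above all RV saline libraries and below the mean of 41.8 ± 20.8 (SD) of RV MCT replicates 1, 2 and 5.

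RV MCT replicate 4, at -30.3, also lay among the saline libraries, without being far enough from its group to be picked out. Low depth is argued against, since 4 of the other 4 RV MCT libraries stayed above the highest RV saline library after thinning. The share of the top genes predicted a score of at least -25.0, so it falls short as the whole cause, by a small margin. A weak response of the animal in both ventricles is argued against if the numbers mark animals, since LV MCT replicate 4 scored 28.5. A library from another animal may explain it: RV and LV MCT replicate 4 differed at 3 of the 8 on-off genes, against 0 or 1 in the other MCT pairs, but no LV library differed from RV MCT replicate 4 at fewer than 2, and the genes are few. A weak response of this RV alone was not tested.

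For the LV response, 1 of 100 splits of the libraries, the real one, called as many as 1040 genes, and the highest other called 535. Chance is therefore unlikely for this count, though 100 splits cannot exclude it. All other splits with any call exchanged LV MCT replicate 3 with a single saline library. For the RV response, 3 of 100 splits, the real one included, called at least 30 genes. That is few, but the others among these called 505 and 125, more than the real one. Chance is therefore less likely but not excluded for this count. The count itself is not stable, since it was 0 with the RV libraries alone and 0 to 3 without any of 7 single libraries. The highest other split called 505 after an exchange of RV MCT replicate 4 with RV saline replicate 1, many times the real count. This points to a structure of the samples. Only 100 of the 126 possible splits were used, the real one included. An exchange of RV MCT replicate 4 with RV saline replicate 2 or 3 alone was not among them, so other splits with many calls may have been missed. The exchange with RV saline replicate 5 alone called 7 genes. Whether RV MCT replicate 4 and RV saline replicate 1 were exchanged was not tested and stays open. RV saline replicate 1 scored -9.61 on the first component, the highest of the saline libraries but below the other 4 RV MCT libraries. Genes higher after MCT in the LV held 1.58% of its counts, against 1.05% to 1.20% in the other RV saline libraries. In the other 4 RV MCT libraries they held more, 2.01% to 3.53%. At the on-off genes RV MCT replicate 4 differed least from LV saline replicate 1, at 2 genes. Other values go against it. ENSRNOG00000019719, chosen in the LV, was at 40.8 CPM in RV saline replicate 1, against 1.11 to 21.5 CPM in RV MCT libraries, and the description codes of both libraries read as different months. An exchange of RV MCT replicate 4 with RV saline replicate 4 also called 125 genes, so a high count does not mark which labels were exchanged. Those libraries carry the same date-like code, so the codes do not go against that exchange, which was not tested. RV saline replicate 4 scored -17.4 on the first component, among the saline libraries. For RV against LV after saline, 1 of 100 splits called as many as 8 genes and the highest other called 0, though these splits exchange libraries without regard to their numbers. For both comparisons with 0 calls, 100 of 100 splits call as many by construction, so the splits say nothing about chance there. The highest other split called 6 genes for the difference of the responses. For RV against LV after MCT it called 377, which points to a structure within the MCT libraries.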

How the results depend on the processing

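2 alternatives were chosen after seeing the data: leaving out LV MCT replicate 3 with RV MCT replicate 4, and the share of the 2 top genes as a covariate. The first drops libraries because they looked unaffected, which favours calls, so its counts are no estimate of the effect. Without both libraries the RV count was 1076, the LV count 2016, the difference of responses 1, and RV against LV after saline 44. With the covariate they were 251, 1592, 0 and 28.

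The RV count of 30 was 18 without a filter, 19 with the month term, 0 with the RV groups alone, 378 with DESeq2 and 253 with limma voom, and leaving out 1 library gave 0 to 707. The LV count of 1040 was 2892 with limma voom, and leaving out 1 library gave 331 to 1699. After saline, RV against LV gave 8 genes, 13 with RLE, 80 with the saline groups alone, 88 with DESeq2 and 114 with limma voom, and 0 to 11 with 1 library left out. After MCT it gave 0 genes, and 0 to 2 with 1 library left out. The difference of responses was 0 in all fits fixed beforehand except DESeq2, which called 1. The cause was not tested in any of these.

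With the replicate number as a block, the RV count was 0 and the LV count 356. With each same-numbered RV and LV pair as a block, the difference of responses gave 0, and RV against LV gave 9 after saline and 0 after MCT. Of the 8 genes called after saline without the block, 2 were among those 9, so most of these genes depend on the block. Same-numbered MCT and saline libraries did not all deviate together: the correlations of their deviations from the group means ran from -0.31 to 0.25 in the RV and from -0.34 to 0.27 in the LV. For same-numbered RV and LV libraries they ran from -0.43 to 0.26 after MCT and from -0.25 to 0.69 after saline. The RV library correlated best with the LV library of its number only in replicate 3 after MCT and replicates 2, 4 and 5 after saline. Calls lost under the block that joins MCT and saline numbers are therefore not read as a weaker effect. After saline some RV and LV pairs did correlate, so the loss of most of the 8 genes stays a limit of that result.

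The correlation of the responses, 0.75, was 0.31 without a filter on low counts. It was 0.69 to 0.74 with 1 same-numbered RV and LV pair left out. With separate replicate numbers for each ventricle, and so means of only 2 or 3 libraries, it was 0.54 and 0.57. The 4 genes printed by ID kept their direction in all 20 alternatives of each ventricle. The RV call of ENSRNOG00000002434 was lost in 10 of 20 and that of ENSRNOG00000009325 in 9 of 20. The LV calls of ENSRNOG00000019719 and ENSRNOG00000002916 were lost in 7 and 9 of 20. The alternatives fixed beforehand for gene lists and for genes fixed by symbol were not run, since no symbols were at hand.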

Other observations

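The tests of both hypotheses here, and the criteria for on-off genes, were chosen after the results were seen, and the bound for the ventricles becoming more alike was changed once after its outcome was known. At equal total counts, more genes were detected in LV MCT libraries, 14151 ± 225 (SD, n = 5), than in LV saline libraries, 13494 ± 107 (exact two-sided permutation p = 0.0079, the smallest that 5 against 5 allows). The Benjamini-Hochberg value over 10 relations was 0.079, so the difference failed the correction. The 10 top genes took 35.8% of the counts in LV MCT and 42.3% in LV saline libraries, so the counts left for other genes were not equal. In the RV the values were 14120 ± 192 and 13828 ± 172 (exact permutation p = 0.056, Benjamini-Hochberg value 0.14).

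Same-numbered RV and LV MCT libraries may come from 1 animal each. On-off genes had a gap of at least 1.5 log2 units between a lower and an upper side of the saline libraries. The upper side had a mean log2 CPM of at least 2, and both saline libraries of each number lay on the same side. Genes on the lower side could still be expressed. At the 8 genes found, same-numbered MCT libraries differed 6 times in all. Of the 120 pairings of RV with LV MCT libraries, 2 had as few differences (exact one-sided permutation p = 0.017). Same-numbered libraries also share the date-like code, and these pairings mix libraries of different months. A difference between dates could therefore give the same result without shared animals. The genes were chosen in saline libraries only, and expression can shift a gene between these sides within an animal. Correlations of the deviations from the group means, over 6890 genes, give little support after MCT, but they cannot decide the question. Libraries that deviate as a whole can correlate whether or not they share an animal. Only RV MCT replicate 3 correlated best with the LV MCT library of its number. RV MCT replicate 4 correlated at -0.34 with LV MCT replicate 4 and at 0.68 with LV MCT replicate 3. Both RV MCT replicate 4 and LV MCT replicate 3 lay among the saline libraries on the first component. After saline, replicates 2, 4 and 5 correlated best with their own number.

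Fewer genes differed between RV and LV after MCT than after saline, and MCT may make the ventricles more alike. The median absolute log2 difference was 0.13 after MCT and 0.18 after saline. Over the 252 splits of the 10 same-numbered RV and LV pairs, which the labels do not call animals, the fall had an exact one-sided permutation p = 0.052, which misses 0.05, so the hypothesis stays open.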
